A study of Homo sapiens with 12 samples.

How the data were processed

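Total RNA from MCF7 cells was extracted with a Zymo column kit, and libraries were made with the Illumina TruSeq Stranded Total RNA Gold kit, per the labels. The values analysed were raw gene counts deposited by the authors, 1 count per gene and library, in a table of 28395 genes keyed by Entrez identifiers. Per the submitters' processing notes, STAR, R 3.6 and limma were used with GRCh38. The roles and order of these tools, the counting tool, its annotation and its strand setting were not given in the sources used here. Symbols, positions and biotypes were added from the RefSeq gene tables and GENCODE 29. Of the identifiers, 27745 were matched to a symbol and 650 were not; unmatched genes were kept in the library totals.

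The 12 libraries formed 4 groups of 3: TRIB1 siRNA, non-targeting siRNA, TRIB1 shRNA clone and non-targeting shRNA clone. Totals ran from 16674592 to 21279725 counts. Between replicates of a group, Pearson r of log CPM was 0.993 to 0.995. The chi-square per degree of freedom against counting error alone was 2.78 to 14.6, so that replicates varied more than counting error. Counting intervals given for single genes cover counting error only.

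Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 14506. Libraries were scaled by TMM over the tested genes, as are all CPM given here, and edgeR's quasi-likelihood test was fitted to all 12 libraries with a mean per group and 8 residual degrees of freedom. The common dispersion was 0.00429, a biological coefficient of variation of 0.0655, with 10.9 prior degrees of freedom. The contrasts tested were TRIB1 siRNA minus its control, TRIB1 shRNA minus its control, and the shRNA effect minus the siRNA effect. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with 0.05 as the threshold, and "changed", "rose" and "fell" refer to it. Standard errors are those of the log2 fold changes.

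The 25 gene lists, with 606 entries that all matched, and the rule for the genes named were fixed before the data were examined. Named genes are TRIB1, the 10 largest rises and 10 largest falls per comparison, up to 4 members per list with the smallest adjusted p, up to 10 genes changed alike and 5 changed oppositely in both comparisons, and the 5 largest differences in each direction. The largest changes needed a mean of at least 5 CPM and all 3 libraries of a group above all 3 of the other, which 10% of genes would show by chance. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Members were counted with p-values adjusted over all genes, and again adjusted over the list alone.

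Tested genes with a position were ordered along chromosomes 1 to 22 and X and divided into 289 runs of about 50 genes. The share of the variance of log2 fold changes held by the runs was set against 1000 shuffles of gene positions. Trends on GC content and transcript length were fitted with mgcv 1.9.3. Overlaps of changed genes were tested with a two-sided Fisher's exact test.

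Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. In the shRNA arm the same-numbered pairs had correlations of 0.174, 0.275 and 0.179, every pair over 0.1, so those numbers were taken to pair the libraries. The pairing comes from the data, since the labels name no shared batch. The main fit has no term for it, and the pairing entered only as the replicate block among the alternatives.

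The alternatives were DESeq2 1.42.0, limma-voom, median-ratio, upper quartile and library total scaling, no count filter, a filter of 1 CPM in 3 libraries, fits of the 6 libraries of a comparison alone, the replicate number as a block, a minimum fold of 1.5, runs of 25 and 100 genes, and leaving out each library in turn. Chromosome 10 left out, fold changes relative to the run of 50 neighbours, run medians without histone genes, and mitochondrial and small structural RNA left out were added after the data were seen. The pipeline was tested on simulated data with known changes. A 2-fold change was recovered for 94% of genes in the siRNA contrast, 86% in the shRNA contrast and 79% in the difference, and a 1.2-fold change for 20%, 18% and 4%. The simulation changed 50 genes per fold and method, far fewer than changed in the data. The Benjamini-Hochberg threshold depends on that number, so these shares do not carry over to the data. False calls made up 5.52%, 8.84% and 5.76% of calls. A list shifted in the simulation, the endoplasmic reticulum chaperones, was called in the siRNA contrast and the difference, and 0 other lists were. Simulated genes varied independently of each other, whereas the estimated correlation of the chaperones in the data was 0.447. The simulation therefore cannot show how often the list test errs in the data. Without a position effect the simulated runs held 2.31% of the variance (permutation p = 0.036), and 12.7% with chromosome 10 lowered. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used. No sample was left out.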

Results

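RNA abundance was measured by sequencing of total RNA from MCF7 cells, a human breast cancer line that expresses the estrogen receptor, after knockdown of TRIB1. TRIB1 is a pseudokinase of the Tribbles family that brings substrate proteins to a ubiquitin ligase. Knockdown was carried out by 2 methods. In the transient arm, cells received a pool of siRNAs against TRIB1 or a non-targeting pool, 25 pmol each, for 48 h. In the stable arm, 1 clonal line with an inducible shRNA against TRIB1 and 1 clonal line with a non-targeting shRNA were both given 2 µg/mL doxycycline for 48 h. The 4 groups held 3 libraries each, titled as biological replicates, and the 12 libraries had totals of 16674592 to 21279725 counts. Of 28395 listed genes, 25418 had a count in any library and 14506 were tested. P-values of single genes measure the spread between these samples of 1 cell line, with 1 clone per shRNA arm. List tests compare the genes of a list with all other genes, and Fisher's exact tests and shuffles of gene positions take genes as units. None of these p-values measures the spread between clones or cell lines.

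TRIB1 (Entrez gene 10221, GRCh38 chromosome 8, bases 125430358 to 125438403) was examined first in every library, since it is the targeted gene. Its level was 14.88, 13.01 and 15.28 CPM (counts scaled by TMM over the tested genes, as are all CPM here) in the 3 TRIB1 siRNA libraries and 19.58, 19.18 and 20.22 CPM in the 3 non-targeting siRNA libraries. It was 11.35, 11.33 and 11.52 CPM in the TRIB1 shRNA clone and 16.36, 16.32 and 15.23 CPM in the non-targeting shRNA clone. TRIB1 therefore lay lower in each of the 6 knockdown libraries than in any library of the matching control. With siRNA the mean went from 19.7 ± 0.523 to 14.4 ± 1.21 CPM (SD, n = 3), a log2 fold change of -0.45 (SE 0.08, edgeR quasi-likelihood adjusted p = 0.000248), or 26.8% lower with a 95% interval of 17.3% to 35.1%. With shRNA it went from 15.97 ± 0.644 to 11.4 ± 0.102 CPM, a log2 fold change of -0.49 (SE 0.09, adjusted p = 0.000267), or 28.6% lower with an interval of 19.1% to 37.0%. The effects of both methods on TRIB1 differed by -0.04 on the log2 scale, with a 95% interval of -0.29 to 0.21. In a test against a minimum fold of 1.5, TRIB1 no longer passed with either method. With siRNA, 1840 other genes fell by more than TRIB1 did, and 846 did so with shRNA.

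**Figure D1:**
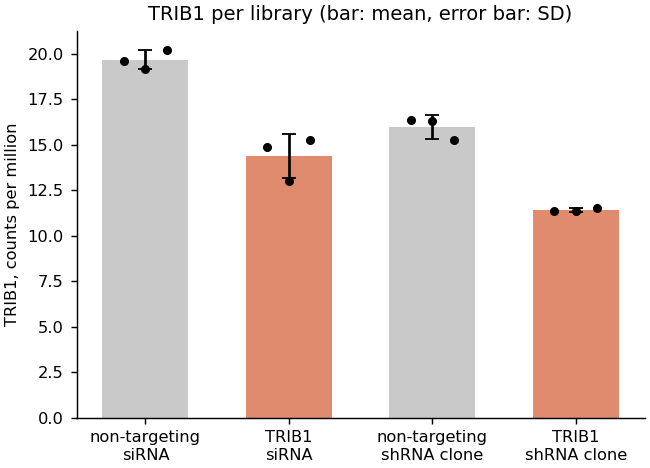
TRIB1 in CPM (vertical axis) in the 4 groups; bars give the mean, error bars the SD and points the 3 libraries of each group. The TRIB1 siRNA libraries lie between 13.01 and 15.28 and their controls between 19.18 and 20.22, and the TRIB1 shRNA libraries lie between 11.33 and 11.52 and their controls between 15.23 and 16.36.

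The comparison of TRIB1 siRNA with non-targeting siRNA asked which genes changed after transient knockdown. BMP7, a secreted growth factor of the transforming growth factor beta family, fell from 201.6 to 47.3 CPM (log2 fold change -2.09, SE 0.09, adjusted p = 7.34e-12). ENO2, the neuronal form of the glycolytic enzyme enolase, fell from 12.5 to 2.38 CPM (-2.38, SE 0.13). The cyclin gene CCND3 fell from 38.5 to 11.1 CPM (-1.79, SE 0.10) and the anti-apoptotic gene BCL2 from 194.9 to 88.3 CPM (-1.14, SE 0.07). Of 18 chaperone and folding enzyme genes of the endoplasmic reticulum 14 fell, each by less than 2-fold, and 1 rose, while BMF, a pro-apoptotic member of the BCL2 family, rose from 4.96 to 15.3 CPM (1.63, SE 0.14).

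In total 6246 genes changed, 43.06% of those tested, of which 2961 were higher and 3285 lower in the TRIB1 siRNA group. Changes of at least 2-fold were seen in 246 of the higher and 597 of the lower genes. Scaled by library totals alone, 33.61% of the changed genes were higher in place of 47.41%. The other large falls were in SCARA3, a scavenger receptor gene (10.96 to 1.96 CPM, log2 fold change -2.48), FAM20C, a kinase gene of the secretory pathway (-2.32), SLAIN1, a microtubule-binding protein gene (-2.28), SGCB, which encodes beta-sarcoglycan (-2.15), ATP11C, a phospholipid flippase gene (-2.06), RAB31, a small GTPase gene (-2.05), EI24 (150.7 to 39.6 CPM, -1.93) and the cytokine gene IL20 (-1.92). The largest rise of the selected genes was in ATP6V0A4, a subunit gene of the vacuolar proton pump (2.67 to 13.65 CPM, 2.35). Rises were also seen in the poly(A) polymerase gene TENT5C (1.80), in ELF5, a transcription factor gene of mammary secretory cells (1.71), UNC13D, a vesicle priming gene (1.61), SP6 (1.51), the adhesion gene NECTIN4 (1.49), the peptidylarginine deiminase gene PADI2 (1.48) and the lipid kinase gene PIK3C2G (1.45). The mitochondrial ribosomal RNA MT-RNR2 also rose (2.15, SE 0.30), with 525.5, 1617 and 2375 CPM in the TRIB1 siRNA libraries against 313.4, 320.0 and 382.7 CPM in the controls.

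Of 25 gene lists fixed before the data were examined, 4 passed a test of each list against all other genes (limma's camera with a preset correlation of 0.01). Endoplasmic reticulum chaperones and folding enzymes were lower: 14 of 18 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone, and the list had an adjusted p = 0.00197, but adjusted p = 0.867 with an estimated correlation. CRELD2 fell by 0.86, PDIA6 by 0.48, PDIA3 by 0.45 and PDIA4 by 0.38 on the log2 scale. PDIA6 and PDIA3 share 25.19% and 14.79% of their exonic bases with ATP6V1C2 and ELL3 on the opposite strand, and the strand setting of the counting was not given in the sources used here. Genes of hypoxia and glycolysis were lower too: 13 of 24 fell, 3 rose and 8 did not pass, again with the same counts adjusted over the list alone (list adjusted p = 0.031, and adjusted p = 0.686 with an estimated correlation). Besides ENO2, the oxygen-sensing hydroxylase gene EGLN3 (-1.34), the phosphoglycerate kinase gene PGK1 (-0.59) and PFKFB3, a regulator of glycolytic flux (-0.65), fell.

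Of 45 DNA replication and E2F target genes, 16 fell, 4 rose and 25 did not pass, also when adjusted over the list alone (list adjusted p = 0.0431, and adjusted p = 0.867 with an estimated correlation). Scaled by library totals, 24 fell and 3 rose. The replicative helicase genes MCM3 (-0.71) and MCM6 (-0.44), GINS2 (-0.51) and the transcription factor gene E2F2 (-0.71) fell. Of 13 mitochondrially encoded protein genes, 8 rose and 5 did not pass, with 10 higher when adjusted over the list alone (list adjusted p = 0.0431, and adjusted p = 0.867 with an estimated correlation). Scaled by library totals, 3 of the 13 were higher. MT-ND5 rose by 0.46, MT-ND6 by 0.46 and MT-COX1 by 0.51. In the same libraries the share of all counts in mitochondrial genes was 0.933% ± 0.142 (SD, n = 3) against 0.652% ± 0.0649 in the controls. That share includes the mitochondrial ribosomal RNAs, which were uneven among the TRIB1 siRNA libraries (MT-RNR1 had 933, 7145 and 14291 counts, and MT-RNR2 9712, 28337 and 41958). The share of RN7SK, a small nuclear RNA, was 4.31% ± 0.374 against 3.19% ± 0.182. Left out one library at a time, the chaperones passed in each of the 6 fits. The other 3 lists were lost without non-targeting siRNA replicate 2 (adjusted p = 0.0522 each). DNA replication genes were also lost without TRIB1 siRNA replicate 1 (0.0851) or non-targeting replicate 3 (0.0598). The mitochondrial genes were also lost without TRIB1 siRNA replicate 2 (0.09) or replicate 3 (0.116), or non-targeting replicate 1 (0.126).

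The other 21 lists did not pass the list test in the siRNA comparison (adjusted p = 0.0885 to 0.819). Members of each changed one by one, but so did 43.06% of all tested genes, and counts near or under that share set no list apart. Among G1 cyclins, cyclin-dependent kinases and their inhibitors, 8 of 21 fell and 1 rose: the inhibitor gene CDKN1B fell from 111.2 to 58.4 CPM (-0.93) and CCND1 fell by 0.45, beside an opposite-strand neighbour, LTO1, that covers 10.29% of its exonic bases, while E2F3 rose by 0.49. Of 38 mitosis and G2/M genes 8 fell and 3 rose, or 13 and 2 scaled by library totals, with CENPA, the centromeric histone gene, at -0.93, the mitotic regulator gene FOXM1 at -0.84 and CDC20 at -0.58; CENPA shares 6.96% of its exonic bases with SLC35F6 and FOXM1 15.94% with ITFG2. p53 targets went both ways, with 8 of 29 higher and 7 lower: BTG2 rose by 1.34 and SESN1 by 0.49, and PHLDA3 fell by 0.95 and RRM2B by 0.39. Of 15 BCL2 family genes 3 rose, among them MCL1 (0.50), and 5 fell, among them PMAIP1 (-0.76). Of 17 death receptor apoptosis genes 7 fell and 4 rose, with CASP7 at -0.58 and TNFRSF10A, a receptor gene for the ligand TRAIL, at -0.79.

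Among AP-1 and immediate early genes, 9 of 21 rose and 2 fell: FOSL2 rose by 0.82, JUND by 0.51 and ZFP36 by 0.98. JUNB rose by 0.70, with 14.23% of its exonic bases under HOOK2 on the opposite strand. Of 18 genes of ERK pathway output 6 fell, such as EPHA2 (-1.09), and 1 rose, the receptor gene EPHA4 (1.28). Of 30 estrogen response genes 7 fell and 3 rose, with TFF1 down from 532.2 to 288.4 CPM (-0.88) and the small heat shock protein gene HSPB8 down from 163.7 to 61.3 CPM (-1.42). Luminal identity genes numbered 4 lower and 3 higher of 19, where the androgen receptor gene AR fell by 0.61 and ERBB3 rose by 0.57. Basal and mesenchymal genes numbered 2 higher and 2 lower of 9, with VIM up (1.03) and CD44 and ITGA6 down (-0.96 and -1.37); VIM shares 12.43% of its exonic bases with VIM-AS1 on the opposite strand. Of 30 interferon and double-stranded RNA response genes 11 fell and 8 rose, or 12 and 5 scaled by library totals; PARP14 fell by 1.43, DTX3L by 1.18 and BST2 by 0.91. Of 19 NF-kB targets 5 fell, such as TNFAIP2 (-1.20), and 2 rose, among them SOD2 (0.37).

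Of 27 genes of the ATF4 and amino acid response 8 rose, among them the serine synthesis gene PHGDH (0.50), and 5 fell, among them JDP2 (-0.96). Of 25 cholesterol synthesis genes 7 rose and 5 fell: the regulator gene SREBF2 rose by 0.56 and MSMO1 by 0.55. Scaled by library totals alone, these became 6 higher and 9 lower for the ATF4 list and 5 higher and 6 lower for cholesterol synthesis, and p53 targets became 5 higher and 8 lower. Of 25 genes of fatty acid and triglyceride metabolism 7 fell and 4 rose, or 10 and 2 scaled by library totals, with the acyl-CoA synthetase genes ACSL4 and ACSL1 at -1.51 and -1.11 and the desaturase gene FADS1 at -0.61. Of 15 genes of the Tribbles family and partners 3 fell and 3 rose: besides TRIB1, TRIB2 fell from 1.93 to 0.763 CPM (-1.33) and FOXO1 by 1.03, and TP53 rose by 0.32. Of 31 replication-dependent histone genes 5 fell and 1 rose, or 13 and 0 scaled by library totals; these are near-identical copies between which reads can be split. Of 21 MYC targets and ribosome biogenesis genes 10 fell and 1 rose, with ODC1, the first enzyme gene of polyamine synthesis, at -0.49. Small RNA machinery genes numbered 4 higher and 4 lower of 13, or 2 and 6 scaled by library totals, with DICER1 at 0.31 and PRKRA at -0.50. Lysosome and autophagy genes numbered 4 higher and 3 lower of 20, or 4 and 4 scaled by library totals, with GPNMB at 2.02 from 0.917 to 3.75 CPM and GRN at 0.42. Of 5 tested markers of stromal, endothelial and blood cells 2 rose, VWF, from 0.785 to 2.55 CPM, and PTPRC. PTPRC did not pass with DESeq2 (adjusted p = 0.0501) or without TRIB1 siRNA replicate 1 (0.156) or 2 (0.0847) or non-targeting replicate 1 (0.134) or 2 (0.123). With scaling by library totals, estrogen response genes became 2 higher and 10 lower, the Tribbles list 2 and 4, G1 genes 1 and 10, AP-1 genes 7 and 2, basal and mesenchymal genes 1 and 2 and MYC targets 1 and 12. For these 21 lists, counts adjusted over the list alone differed by at most 1 gene in either direction. The median and the test differed in sign for p53 targets (median -0.02, mean -0.02, test higher), and the mean and the median for NF-kB targets (median 0.02, mean -0.24, test lower) and the Tribbles list (median 0.10, mean -0.08, test higher). Scaled by library totals, the medians of NF-kB targets (-0.06), cholesterol synthesis (-0.05) and lysosome genes (-0.05) turned from positive to negative.

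The comparison of the TRIB1 shRNA clone with the non-targeting shRNA clone asked the same of a stable, induced knockdown. SLFN11, a gene of the DNA damage response, was nearly absent from the TRIB1 clone, with 0, 3 and 1 counts against 426, 612 and 562 (395-fold lower, 95% counting interval 154 to 1452; fitted adjusted p = 9.18e-14). CDKN1A, which encodes the cell cycle inhibitor p21 and is a target of p53, rose from 57.6 to 152.4 CPM (log2 fold change 1.40, SE 0.10, adjusted p = 4.09e-09), and 13 of 29 p53 targets rose. Of 45 DNA replication genes 27 fell and 2 rose, and of 31 histone genes 12 fell, each of these falls by less than 2-fold. Genes on chromosome 10 had a median log2 fold change of -0.41 in the TRIB1 clone, with little change over part of the chromosome.

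In total 3707 genes changed, 25.55% of those tested, with 1866 higher and 1841 lower in the TRIB1 clone. Of these, 323 of the higher and 244 of the lower genes changed at least 2-fold. The fit left out the pairing of the shRNA libraries, and more genes changed with the replicate number as a block, as given below. The largest falls of the selected genes after SLFN11 were in SMIM22, a small membrane protein gene (22.05 to 2.27 CPM, log2 fold change -3.28), the microRNA precursor gene MIR196A2 (19.3 to 2.45 CPM, -3.00) and OAT, which encodes ornithine aminotransferase (68.8 to 8.98 CPM, -2.94). MIR196A2 had 0 counts in all 6 siRNA libraries of the same cell line. It had 44, 37 and 60 counts in the TRIB1 clone and 347, 381 and 423 in the non-targeting clone. Whether these reads come from the cell's own MIR196A2 gene was not tested. Falls followed in ELOVL2, a fatty acid elongase gene (54.8 to 8.14 CPM, -2.74), the nucleotide receptor gene P2RY6 (-2.50), PRTFDC1 (-2.44), the potassium channel gene KCNK5 (-2.29), WIPF1 (-2.01) and the protease gene TMPRSS4 (-1.96). OAT and PRTFDC1 lie on chromosome 10, but their falls exceeded its median. The largest rises were in PKIA, an inhibitor gene of protein kinase A (1.46 to 35.9 CPM, 4.56), SULF1, a heparan sulfate sulfatase gene (4.14 to 96.3 CPM, 4.54), the synaptic adhesion gene LRFN5 (4.07 to 90.2 CPM, 4.48), and the imprinted gene PEG10 (1.44 to 32.5 CPM, 4.46). Rises of 4.09 for the neuroendocrine transcription factor gene ASCL1, 3.72 for LRATD1, 3.70 for the catenin gene CTNND2, 3.68 for the calprotectin subunit gene S100A9 and 3.61 for CADPS2 came next. UGT2B15, a steroid glucuronidation gene, rose by 3.63, with near-identical paralogs that can share its reads.

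**Figure D2:**
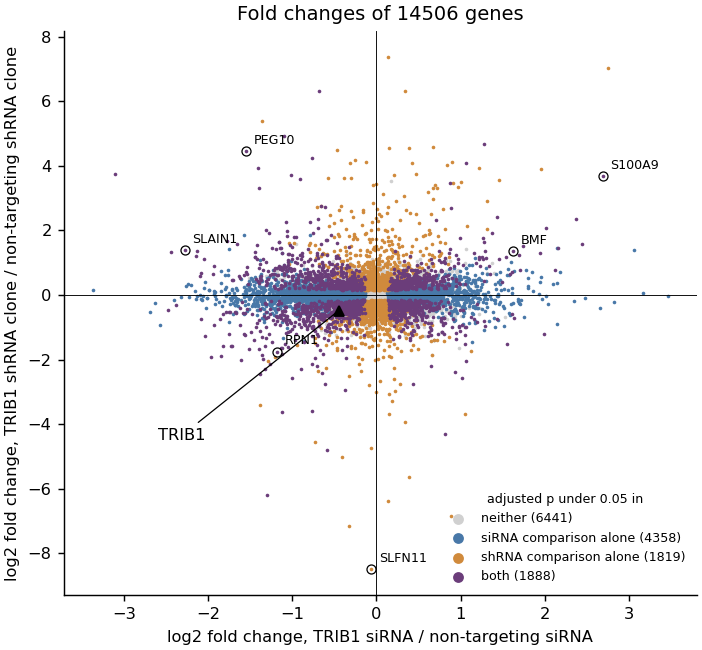
Log2 fold changes of the 14506 tested genes in the siRNA comparison (horizontal axis) and the shRNA comparison (vertical axis), coloured by the comparison in which the adjusted p passed. The points form a cross about the axes, with 1888 genes passing in both, and TRIB1 lies at -0.45 and -0.49.

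Of the 25 lists, 3 passed the list test in the shRNA comparison, and none did with an estimated correlation. Of 45 DNA replication and E2F target genes, 27 fell, 2 rose and 16 did not pass, with 29 lower and 2 higher adjusted over the list alone (list adjusted p = 4.33e-08, and adjusted p = 0.511 with an estimated correlation). UHRF1, a regulator of DNA methylation maintenance, fell by 0.58, the ribonucleotide reductase gene RRM2 by 0.46, E2F1 by 0.56 and MCM3 by 0.38. Of 31 replication-dependent histone genes 12 fell and 19 did not pass, with 17 lower adjusted over the list alone (list adjusted p = 3.7e-06, and adjusted p = 0.955 with an estimated correlation). H2BC9 fell by 0.77, H4C1 by 0.63, H3C7 by 0.57 and H2AC16 by 0.44, where reads can be split between near-identical copies. The list had a median of -0.22. Relative to the median of each gene's chromosomal run it lay at -0.04 and did not pass (adjusted p = 0.228), but histone genes made up 28 and 18 of the 50 genes in a pair of these runs, so that their own fall was subtracted. With histone genes left out of the run medians, a setting added after this loss was seen, the list lay at -0.17 and passed (adjusted p = 7.53e-05, and adjusted p = 0.868 with an estimated correlation). Of 29 p53 targets 13 rose, 1 fell and 15 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.000557, and adjusted p = 0.511 with an estimated correlation). Besides CDKN1A, the receptor gene EDA2R (2.31), the growth regulator gene TP53INP1 (1.23) and BTG2 (0.88) rose.

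The remaining 22 lists did not pass the list test in the shRNA comparison (adjusted p = 0.356 to 0.946). Of all tested genes 25.55% changed in this comparison, and counts of members near or under that share set no list apart. Among G1 cyclins, cyclin-dependent kinases and their inhibitors, 4 of 21 rose and 5 fell: the kinase gene CDK6 rose from 3.20 to 15.5 CPM (2.27) and the inhibitor gene CDKN2B by 1.48, and CDKN1B fell by 0.31. Of 38 mitosis and G2/M genes 7 fell and 3 rose, with CDK1, on chromosome 10, down from 223.5 to 86.1 CPM (-1.38), KIF11, also on chromosome 10, at -0.58, and ANLN, the gene of the cytokinesis scaffold anillin, at 0.56. Of 17 death receptor apoptosis genes 3 rose and 1 fell, with TNFRSF1A at 0.41, CASP8 at 0.36 and CASP7, on chromosome 10, at -0.67, or -0.17 relative to its run of 50 neighbours (adjusted p = 0.104). Of 15 BCL2 family genes 2 rose, BMF (1.36) and PMAIP1 (0.94), and 2 fell, with BCL2 down from 176.3 to 113.2 CPM (-0.64). AP-1 and immediate early genes numbered 3 higher and 5 lower of 21, or 8 higher and 5 lower adjusted over the list alone, with FOSL2 at 0.58 and IER3 at -0.38, or -0.19 relative to its run (adjusted p = 0.0765). Of 18 genes of ERK pathway output 4 rose and 3 fell: EPHA4 rose from 17.8 to 55.2 CPM (1.64) and SPRED1 by 1.45, and PHLDA1 fell by 1.52.

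Estrogen response genes went both ways, with 11 of 30 higher and 12 lower, or 11 and 14 adjusted over the list alone. The growth factor gene AREG rose from 3.95 to 17.7 CPM (2.17), OLFM1 fell by 0.99 and the chemokine gene CXCL12, on chromosome 10, by 1.29. Luminal identity genes numbered 4 higher and 5 lower of 19: AGR2 rose from 8.085 to 52.998 CPM (2.71) and TFF3 by 1.23, and the estrogen receptor gene ESR1 fell from 299.4 to 204.8 CPM (-0.55). Of 9 basal and mesenchymal genes 5 rose, among them the fibronectin gene FN1 (4.63 to 17.2 CPM, 1.89) and the vimentin gene VIM (0.94, with the same opposite-strand overlap), and 1 fell. Of 19 NF-kB targets 1 rose, TNFAIP2 (0.83), and 2 fell, one of them NFKB2 on chromosome 10 (-1.09); with the replicate number as a block NFKBIE passed too (-0.32, adjusted p = 0.0117). Of 30 interferon and double-stranded RNA response genes 4 rose and 5 fell, or 5 and 4 scaled by library totals; SAMD9 rose from 1.12 to 8.85 CPM (2.98) and BST2 by 1.24, and IFI44L was 21.2-fold lower by its counts (95% counting interval 8.001 to 79.7). Of 27 ATF4 and amino acid response genes 6 rose, such as DDIT4 (0.56), and 3 fell. Of 18 endoplasmic reticulum chaperone genes 5 rose, with DNAJB11 at 0.59, and none fell.

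Of 25 cholesterol synthesis genes 4 rose and 6 fell, with STARD4 at 0.48 and PCSK9, which controls the low-density lipoprotein receptor, 13.2-fold lower by its counts (95% counting interval 5.4 to 42.1). Of 25 genes of fatty acid and triglyceride metabolism 5 rose and 4 fell, with ACSL1 at 0.80 and DGAT2 at 0.52. Of 15 genes of the Tribbles family and partners none rose and 2 fell, TRIB1 and the histone deacetylase gene HDAC1 (-0.24, or -0.13 relative to its run, adjusted p = 0.0991). With the replicate number as a block, FOXO1 (0.45, adjusted p = 0.0489) and MAP2K7 (-0.26, adjusted p = 0.0151) passed as well. Hypoxia and glycolysis genes numbered 5 higher and 7 lower of 24: NDRG1 rose by 0.93, and MXI1 and BNIP3, both on chromosome 10, fell by 0.71 and 0.74. Relative to its run, BNIP3 lay at -0.13 and did not pass (adjusted p = 0.325). Of 13 mitochondrially encoded protein genes 3 rose and 3 fell, with MT-ATP6 at 0.50 and MT-ND6 at -0.49. Of 21 MYC targets and ribosome biogenesis genes 1 rose, SRM (0.34), and 3 fell, among them NOLC1 and RRP12 on chromosome 10 (-0.44 and -0.42), both above the median of their runs. Small RNA machinery genes numbered 1 higher and 1 lower of 13, and AGO1 passed with that block (0.18, adjusted p = 0.0293). Of 20 lysosome and autophagy genes 7 rose, such as the cathepsin genes CTSL (0.64) and CTSD (0.43) and GPNMB (2.07), and 3 fell. None of the 5 tested markers of stromal, endothelial and blood cells changed. Under library total scaling, MYC targets became 3 higher and 3 lower, the ATF4 list 6 and 1 and hypoxia genes 5 and 5, and 25 DNA replication genes were lower. Where not given above, counts adjusted over the list alone differed by at most 1 gene in either direction. The median and the mean differed in sign for G1 genes (-0.02 and 0.19, test higher), estrogen response (-0.20 and 0.03, test lower), luminal identity (-0.06 and 0.15, test lower), cholesterol synthesis (0.05 and -0.12, test higher) and the Tribbles list (0.03 and -0.02, test lower).

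**Figure D3:**
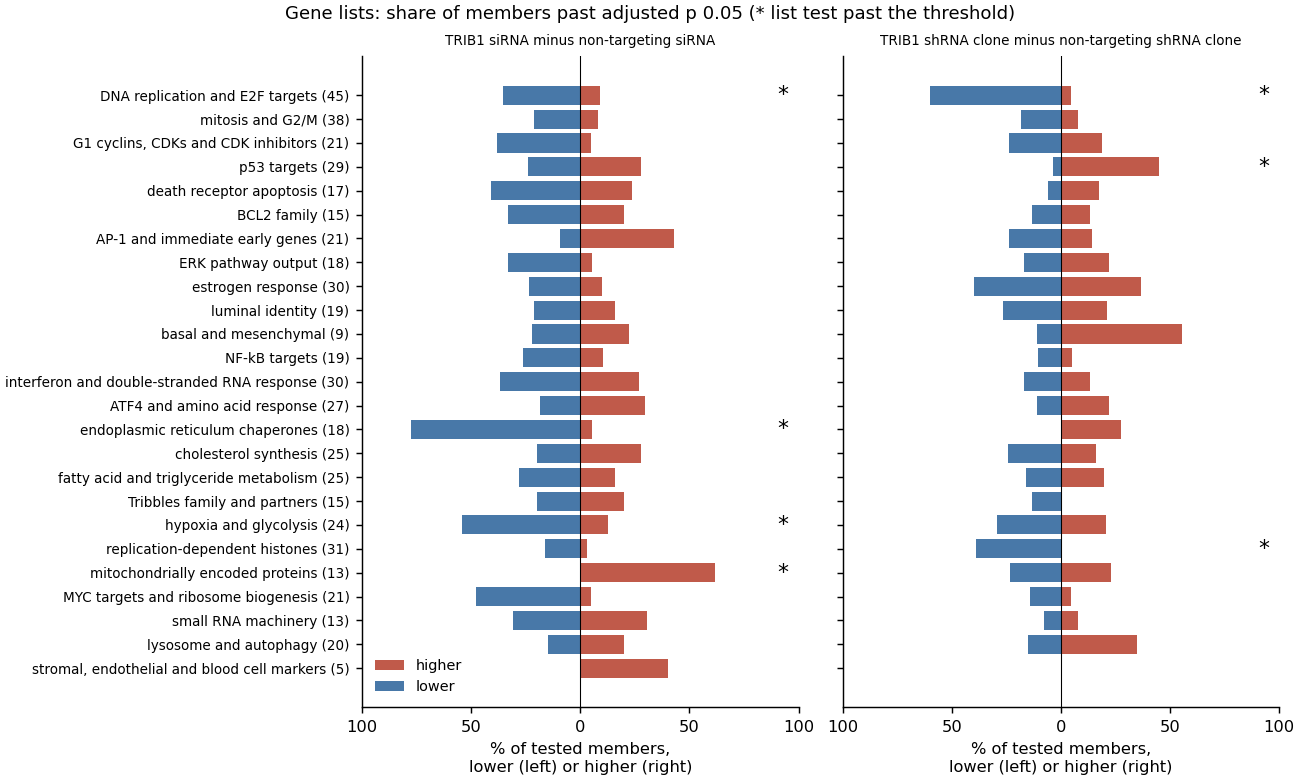
Share of the tested members of each of the 25 gene lists (number tested in brackets) that were higher (to the right) or lower (to the left), in percent, in the siRNA comparison (left panel) and the shRNA comparison (right panel); a star marks lists past the list test. Of the 18 chaperone genes 14 were lower with siRNA, and of the 45 DNA replication genes 27 were lower with shRNA.

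Fold changes were also examined along the chromosomes, because clones of a cell line can differ in whole regions. On chromosome 10, 322 of 566 tested genes were lower in the TRIB1 shRNA clone and 29 higher, and 81.8% had a negative fold change, against 49.3% with siRNA. Of its runs of about 50 neighbouring genes, those at 10:14518557 to 27154384 and 10:27154479 to 45672813 moved little (medians -0.09 and -0.02, with 8 and 5 genes lower and 8 and 4 higher). The median of its genes relative to the non-targeting siRNA libraries was -0.44, -0.42 and -0.47 in the 3 libraries of the TRIB1 clone and -0.04, -0.02 and -0.05 in those of the non-targeting clone. The run of 50 neighbouring genes that lay lowest was at 10:100486647 to 104126383 (median -0.67, 44 of 50 lower), and the highest runs were at 7:44143213 to 65770810 (0.46, 38 of 50 higher), 3:169766921 to 184184091 (0.42) and 15:90884504 to 101976605 (0.37). Runs of 50 genes held 11.5% of the variance of shRNA log2 fold changes, above all of 1000 shuffles of gene positions (1.54% to 2.56%, permutation p = 0.001, the smallest they can give). They held 3.16% with siRNA, also above its shuffles (1.47% to 2.65%, permutation p = 0.001). The run that holds TRIB1 had medians of 0.06 with siRNA and 0.07 with shRNA.

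**Figure D4:**
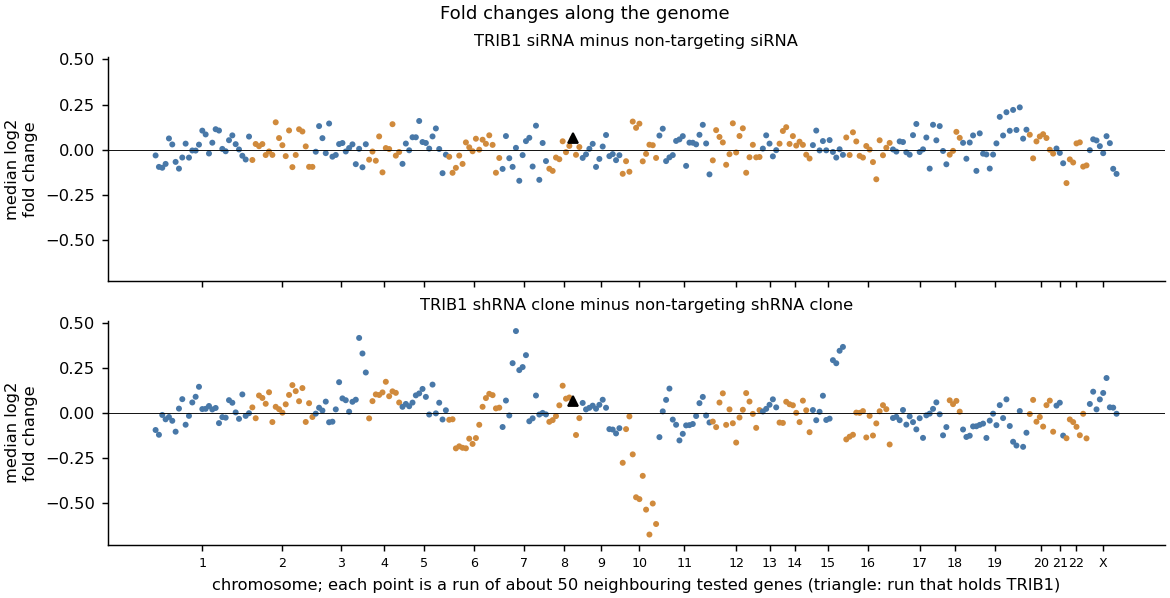
Median log2 fold change (vertical axis) of each run of about 50 neighbouring tested genes, ordered along chromosomes 1 to 22 and X (horizontal axis), for the siRNA comparison (upper panel) and the shRNA comparison (lower panel). In the lower panel, runs on chromosome 10 reach -0.67 and a run on chromosome 7 reaches 0.46; the triangle marks the run that holds TRIB1.

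Both comparisons were then set side by side, to ask which genes changed with either method of knockdown. PGM5, a gene of the phosphoglucomutase family, fell with both (log2 fold changes -1.72 with siRNA and -1.59 with shRNA), as did the intermediate filament gene NES (-1.36 and -1.31), MICB, a ligand gene for a receptor of natural killer cells (-1.56 and -1.23), and RPN1, a subunit gene of the oligosaccharyltransferase (486.6 to 214.7 CPM and 414.4 to 123.0 CPM, -1.18 and -1.75). The nuclear receptor gene NR2F1 (-1.32 and -1.0), the antioxidant enzyme gene GPX3 (-1.43 and -1.0) and PRTFDC1 (-1.39 and -2.44) fell with both as well. BMF (1.63 and 1.36), EPHA4 (1.28 and 1.64) and SYTL5 (1.18 and 1.0) rose with both. Opposite changes were seen for the caveolin gene CAV2 (-1.78 and 1.68), PEG10 (-1.55 and 4.46), ZNF492 (-1.40 and 3.94), LDLRAD4 (-1.40 and 3.33) and SLAIN1 (-2.28 and 1.38). ZNF492 belongs to a zinc finger family on chromosome 19 whose members can share reads.

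Of the 1888 genes that changed with both methods, 972 changed in the same direction and 916 in opposite directions. Without non-targeting shRNA replicate 1 these became 851 and 882, so the larger of both counts depended on 1 library. Independent lists of these sizes would share 797.8 and 798.4 genes. At least 2-fold changes with both were seen in 109 genes, of which 63 went the same way. Per direction, 553 genes were lower with both against 416.9 of independent lists (two-sided Fisher's exact test, p = 3.03e-15), and 419 were higher with both against 380.9 (p = 0.021). In opposite directions, 528 were lower with siRNA and higher with shRNA against 422.6 (Fisher's exact test, p = 9.77e-10), and 388 were higher with siRNA and lower with shRNA against 375.8 (p = 0.458); genes are not independent replicates, so these p-values describe the lists. With the replicate number as a block, 1721 genes changed in the same direction and 1600 in opposite directions. Across the tested genes the fold changes of both comparisons had a Pearson r of 0.0405 (SE 0.0297 by leaving out each library in turn) and a Spearman rho of 0.0253.

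The difference between the comparisons was tested as the shRNA effect minus the siRNA effect. PEG10 differed by 6.01 on the log2 scale and SLFN11 by -8.43, and 5387 genes differed, 2851 with a higher and 2536 with a lower shRNA effect. Of these, 885 and 434 differed by at least 2-fold, and the higher share was 52.92%, or 66.97% scaled by library totals. Of the 25 lists, the endoplasmic reticulum chaperones differed as a list: 13 of 18 had a higher shRNA effect and 5 did not pass, with 14 higher adjusted over the list alone (list adjusted p = 0.000389, and adjusted p = 0.622 with an estimated correlation). CRELD2 differed by 0.79, DNAJB11 by 0.88 and PDIA6 by 0.56. Of 45 DNA replication genes 4 had a higher and 13 a lower shRNA effect (list adjusted p = 0.231), or 8 and 6 scaled by library totals. For p53 targets, 12 of 29 had a higher and 4 a lower shRNA effect (list adjusted p = 0.231), or 14 and 1 scaled by library totals, with CDKN1A among the former (1.43, adjusted p = 3.58e-07).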

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

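Of the tests in this part, those of unequal loss of TRIB1 RNA and of effects of the siRNA pool or of a clone were chosen after the result was seen, as were the highest r within reach and the counts of splits by pairing. A test of the difference between the effects of both methods singled out 5387 genes. The largest negative differences, shRNA minus siRNA, were in SLFN11 (-8.43), SMIM22 (-3.47), DACH1 (-3.21), MT-RNR1 (-3.10) and CHST3 on chromosome 10 (-2.84). The largest positive ones were in PEG10 (6.01), ZNF492 (5.34), LRFN5 (4.95), LDLRAD4 (4.73) and MARCKS (4.48). MT-RNR1 varied among the TRIB1 siRNA libraries (50.48, 407.6 and 808.9 CPM, against 45.61, 41.86 and 53.82 in the controls). As a list, endoplasmic reticulum chaperones also differed (camera adjusted p = 0.000389, and adjusted p = 0.622 with an estimated correlation).

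The fold changes of both knockdowns were nearly uncorrelated across genes (r = 0.0405), although TRIB1 fell by a similar amount. Counting and replicate noise does not account for this, since fold changes from separate libraries of a comparison had median r of 0.692 with siRNA and 0.66 with shRNA. The difference in TRIB1 was -0.0369 on the log2 scale, with an interval of -0.29 to 0.21. Beside falls in TRIB1 of -0.45 with siRNA and -0.49 with shRNA, that interval is too wide to exclude unequal loss of TRIB1 RNA. Copy number differences between the clones were taken as shifts of whole runs. No change of the run levels could give an r above 0.185, so such shifts cannot have lowered r from above that value. What r would be without copy number differences is not known, so this limit does not decide whether they are a cause. They cannot be told apart from other sources here. Relative to the run of 50 neighbours r was 0.0453, but runs held too little of the variance (11.5% with shRNA and 3.16% with siRNA) for that test to reach the r of 0.2 it needed. Effects of the siRNA pool or of a clone cannot be told apart from those of TRIB1 loss, because the design has 1 clone per arm and 1 pool. A biological difference between transient and stable knockdown stays open as a hypothesis on the same grounds.

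Other splits of the libraries were compared with the real one. For siRNA the real split gave 6246 changed genes and the highest other 0, and for shRNA the real split gave 3707 and the highest other 0. In each case 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05, the smallest being 0.1. Under the pairing of the shRNA libraries, 4 of those splits part every pair, so that the smallest share is 0.25, and the 3 others gave 0 changed genes. For the difference, 1 of 100 splits, the real one, reached 5387 genes, and the highest other gave 3244. These splits were drawn without regard to the shRNA pairing. Of them, 37 part every pair, of which only the real one reached its count, and the highest other gave 2287. Mixing the libraries of a method also removes the effect of that method, so these splits cannot show that both effects differ. The split with the real siRNA groups and the shRNA groups exchanged was not among those drawn.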

How the results depend on the processing

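TRIB1 kept its direction and its call under all scalings, filters and tools, with leave-one-out ranges of -0.50 to -0.38 (siRNA) and -0.52 to -0.47 (shRNA). Only against a minimum fold of 1.5 did TRIB1 no longer pass (-0.45 and -0.49, adjusted p = 1 for both); that setting left 736, 478 and 1125 changed genes for siRNA, shRNA and the difference, and 41 shared in direction, by its construction. Changed genes ran from 5799 to 6915 (siRNA), 2971 to 3878 (shRNA) and 5041 to 5418 (difference) in the other planned settings without a block, and from 5257 to 5587, 2970 to 3644 and 4777 to 5342 without 1 library. Shared genes ran from 845 to 984, and from 795 to 978 without 1 library, and more genes were opposite (882) than shared (851) without non-targeting shRNA replicate 1 alone. Across the genes r was 0.0123 without the low-count filter, 0.0365 to 0.0412 in the other planned settings, and 0.0225 to 0.0507 without 1 library. Settings added after the data were seen gave 3356 (chromosome 10 left out), 2970 (relative to the run of neighbours) and 6211 (without mitochondrial and small structural RNA). Scaled by library totals, 33.61% of siRNA changes and 66.97% of differences were higher. With the replicate number as a block, 7688, 5450 and 6967 genes changed and 1721 were shared in direction, with 1600 opposite; the cause was not tested. The block also brought AP-1 genes with siRNA (adjusted p = 0.0305) and, with shRNA, NFKBIE, FOXO1, MAP2K7 and AGO1 past the threshold, and changed no other call of a named gene or list. Without 1 library in turn, 13 calls of named genes were lost in at least 1 fit, 3 with siRNA and 10 with shRNA. In the siRNA arm, numbers were not taken to pair the libraries. Same-numbered correlations there were 0.139, 0.063 and 0.009, and replicate 3 correlated best with control 2 (0.049). This does not exclude pairing in that arm, where more genes changed with the block too. Of the lists, 0 passed with an estimated correlation in each of siRNA, shRNA and the difference, and fry gave 15, 7 and 8 directional and 24, 24 and 24 mixed. The fry test asks whether members change at all, and camera whether they change more than other genes. With 43.06% (siRNA), 25.55% (shRNA) and 37.14% (difference) of tested genes changed, the mixed counts say little about single lists. What else set these methods apart was not tested. Without 1 library, 1 to 4 lists passed with siRNA, 3 with shRNA and 1 to 2 in the difference. AP-1 genes with siRNA passed without TRIB1 siRNA replicate 2 (adjusted p = 0.0342) or 3 (0.0327) or control 1 (0.0247), and histones in the difference without siRNA control 1 (0.0293) or TRIB1 shRNA replicate 1 (0.0273). Relative to the run of neighbours, GPAM (0.10), NOLC1 (0.23, adjusted p = 0.0241) and RRP12 (0.12), all on chromosome 10, turned from lower to higher by construction. In that setting 10 other named genes no longer passed: CASP7 (-0.17, adjusted p = 0.104), BNIP3 (-0.13, 0.325), IDI1 (-0.07, 0.547), IER3 (-0.19, 0.0765), HDAC1 (-0.13, 0.0991), XPO5 (-0.06, 0.488), ITGA6 (0.30, 0.114), ASNS (0.26, 0.199), SEL1L (0.19, 0.105) and AGO2 (0.18, 0.0809). In the simulation, 1.2-fold changes were recovered for 20% of genes with siRNA. Far fewer genes were changed there than in the data, so this share does not carry over to the data.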

Other observations

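Of the tests in this part, that of reads shared with ribosomal protein pseudogenes was chosen after the result was seen, as were the gene families. Genes for cytosolic ribosomal proteins were higher with siRNA: 73 of 82 rose, 2 fell and 7 did not pass, with a median log2 fold change of 0.41 (camera p = 5.69e-20, and p = 0.0888 with an estimated correlation). With shRNA 4 rose, 19 fell and 59 did not pass (median -0.12), and in the difference 69 had a lower and 2 a higher shRNA effect (median -0.52). Other translation genes whose mRNAs start with a terminal oligopyrimidine tract moved the same way with siRNA, with 17 of 18 higher (camera p = 1.02e-10, and p = 0.0109 with an estimated correlation), and with shRNA 1 rose and 3 fell. Of 427 zinc finger genes 131 were higher and 76 lower with siRNA (median 0.09), and the family did not pass (camera p = 0.0558, and p = 0.156 with an estimated correlation). Those on chromosome 19 were more often higher than lower with siRNA, 72 against 30 of 202 (median 0.15, camera p = 0.00989, and p = 0.204 with an estimated correlation).

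The rise of ribosomal protein genes was weighed against technical causes. A trend on GC content and transcript length does not account for it, with a median of 0.42 after the trend was removed (lower quartile 0.33). Reads shared with pseudogenes cannot be excluded. The other translation genes rose too, at a median of 0.46, but whether those genes lack pseudogenes of their own was not checked. A single aberrant library is argued against by the lowest median without 1 library, 0.37. The TRIB1 siRNA libraries also differed from their controls in composition, with 7.82% against 6.18% of counts in small structural RNA genes, 4.31% against 3.19% in RN7SK and 0.933% against 0.652% in mitochondrial genes. Whether this bears on the rise was not tested. No biological explanation was tested, and the cause stays open.

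The shRNA fold changes ran together along chromosomes. Copy number differences between both clones fit this, with 11.5% of the variance in runs of 50 genes, above all shuffles and above the siRNA share of 3.16%. The share measures the pattern itself, so it does not set copy number apart from other causes. The siRNA share lay above its shuffles too. GC content and transcript length account for at most a part of the shRNA pattern. The shRNA share was 9.13% after their trend was removed and 11.3% before, against at most 2.54% in shuffles. The shRNA fold changes were lower at higher GC content (Spearman rho -0.231, against -0.05 with siRNA). The gene and list results were not corrected for this trend. DNA copy number itself was not measured here, and when such differences arose stays open.

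The immunoglobulin gene IGHG4, chosen after its values were seen, had a mean of 66.4 CPM in the non-targeting clone and 22.7 CPM in the TRIB1 clone, against 1.72 and 1.99 CPM in the siRNA control and TRIB1 libraries.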
